A study of Mus musculus with 16 samples.

How the data were processed

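Dermal fibroblasts, the matrix-producing cells of the skin, came from female C57Bl/6 mice, a widely used inbred laboratory strain. Per the labels, 4 young mice aged 2 months and 4 old mice aged 18 months were used. Each mouse gave 1 sample that was profiled directly after isolation (called in vivo here, the labels' term) and 1 sample that was profiled after culture. The 16 samples therefore form 4 groups of 4 arrays each: young in vivo, old in vivo, young cultured and old cultured. Per the labels' protocols, RNA from 5000 cells per sample was taken up on magnetic beads and amplified as cDNA over 23 cycles, and the labelled cDNA was hybridised to an Affymetrix mouse expression array. The time in culture, the medium and the passage number are not given in the sources used here.

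The deposited table holds 45141 probe sets for 16 arrays, with 2 decimals. The deposited values were treated as log2 intensities. RMA and the package affy are named in the submitters' processing notes, with no version. RMA subtracts background, equalises the distribution of values between arrays and gives 1 value per probe set. The base of the logarithm and whether all 16 arrays were normalised together are not stated, so the base was taken from the range of the values. RMA narrows the differences of dim genes, because every value contains background signal, so a fold change of a gene near background is an underestimate. Equalising the distributions also assumes that the total amount of RNA is alike in all samples, so every change is relative to the other genes on the array. No pair of arrays was identical (0 pairs).

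Of the probe sets, 28898 were listed with 1 gene symbol in the platform annotation, 551 with several and 15692 were not listed (15588 after leaving out Affymetrix control probe sets, which number 104). By gene ID, 28689 probe sets were matched to the RefSeq table of assembly GRCm38.p6, which was used for current symbols and for which genes neighbour each other. Only probe sets with 1 symbol entered the gene tests. Each of the 17097 genes was represented by its probe set with the highest mean over all arrays. A gene was tested if at least 4 of the 16 arrays lay above 3.87 (log2), the 25th percentile of all deposited values, which left 14819 genes. For arrays, the number of samples limits the precision: with 4 against 4 arrays the 70 labelings of an exact permutation test give a smallest two-sided p of 0.0286. As a guide to signal over background, the 12 poly-A control probe sets had a 95th percentile of 4.34, and 3687 tested genes had at least 1 group mean below it.

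Group means were fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) to all 16 arrays, with no block. There were 6 contrasts: culture averaged over both ages, culture in young, culture in old, age in vivo, age in culture, and the interaction, which is the age difference in culture minus the age difference in vivo. All p-values are two-sided and Benjamini-Hochberg adjusted over the genes tested within a contrast, and the threshold was an adjusted p of 0.05. Log2 changes are given with the standard error of the fit unless an SD is named. The 2 age comparisons share no arrays, but in vivo and cultured samples came from the same mice, and the labels do not say which samples share a mouse or a collection day, so no block for mouse or day could be fitted. Per the labels each collection day held as many young as old mice, so day is balanced over age.

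The fit assumes 1 spread per gene for all arrays. The median residual SD was 0.185 (log2) among in vivo arrays and 0.129 among cultured arrays. For the typical gene the shared estimate is therefore too small for comparisons among in vivo arrays and too large for those among cultured arrays. The steps were tested on simulated data with each gene's measured SD in each condition, drawn independently between genes (14819 genes, 200 of them changed, 3 draws). For age in vivo, 28.4% of the simulated calls were false, against 6.11% with only the 8 in vivo arrays in the fit. The shares of false calls were 9.11% for age in culture, 7.63% for the interaction and 4.78% for culture. For age in vivo, 52.2% of genes with a simulated log2 change of 0.5 were recovered and 92.5% of those with a change of 1. For age in culture the shares were 56.2% and 93.5%.

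The gene lists (35 lists of pathways, complexes and fibroblast classes, and 18 lists of cell type markers) were tested with camera at a preset correlation of 0.01, against all other tested genes, with Benjamini-Hochberg adjustment over the lists of a family within a contrast. Camera with an estimated correlation and fry were run beside it. A list needed at least 5 measured genes, which all 35 lists and 12 of the marker lists had; the lymphatic endothelial, mast cell, Schwann cell, adipocyte, erythroid and hair follicle lists had fewer and were not tested. Members past the threshold are counted over all genes tested and "adjusted over the list alone". The gene lists, the contrasts, the tests, the filter and the rule for named genes were fixed before the data were examined. Named genes were, for culture, the 15 highest and 15 lowest changes among genes past the threshold with no overlap between cultured and in vivo values, for each age effect the 12 highest and 12 lowest with no overlap between ages, and for the interaction the 8 highest and 8 lowest. Where no gene passed, the 5 with the smallest p in each direction were taken. Examples from a list were its members past the threshold with the largest change, or where none passed those with the largest change, given as values. Predicted genes and genes with provisional symbols were counted and not named.

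The age differences in vivo and in culture were compared across genes by Pearson's r and Spearman's rho, with exact permutation of the age labels of the cultured arrays. Principal components were computed from the tested genes, centred per gene. Alternatives were no filter, a filter at the median of all values (4.81), the mean over a gene's probe sets, every probe set tested by itself, scaling to the 75th percentile, cyclic loess between arrays, eBayes with trend and robust options, array weights, a threshold with at least a 2-fold change, a threshold of 0.01, only the 8 arrays of the groups compared, and leaving out each array in turn. For culture a fit without age was added, and for lists a test without genes that other lists share. Chosen after the data were seen were 1 weight per culture condition, leaving out the least correlated array of each in vivo group, a block for a split of the cultured arrays found by clustering, list tests on the 8 arrays compared, and exact permutation of list medians. The last was run only for lists past the camera test for an age effect, with no adjustment over lists. Where a scaling moved the median of all genes by over 0.1 (log2), changes are read relative to that shift. Scaling to the 75th percentile moved it by -0.28 for culture, -0.34 for culture in young, -0.21 for culture in old, -0.12 for age in vivo and 0.13 for the interaction.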

Results

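Gene expression was measured on 16 arrays to ask how age-related differences of mouse dermal fibroblasts compare between freshly isolated cells and cells that had been cultured. Young (2 months) and old (18 months) mice gave 4 in vivo and 4 cultured samples each. The median log2 value of an array lay between 4.74 and 4.92. Correlations between arrays were 0.972 to 0.991 within the in vivo arrays, 0.984 to 0.995 within the cultured arrays and 0.840 to 0.884 between the conditions. The first principal component held 85.0% of the variance and separated cultured from in vivo arrays. The second held 3.26%, and along it all young in vivo arrays lay above all old in vivo arrays, while young and old cultured arrays were intermixed. The difference between 3' and 5' probe sets of beta-actin, a measure of RNA integrity and of amplification length, was -0.41 ± 0.07 (SD, log2, n = 4) in young in vivo, -0.46 ± 0.11 in old in vivo, 0.07 ± 0.04 in young cultured and 0.10 ± 0.07 in old cultured samples. It thus differed with culture, and between the ages by less than the spread between samples. The same difference for Gapdh was -0.08 ± 0.03 (SD, n = 4, -0.12 to -0.04) in young in vivo and -0.14 ± 0.02 (-0.17 to -0.13) in old in vivo samples, with no overlap between the ages. In cultured samples it was -0.10 ± 0.06 in young and -0.15 ± 0.02 in old.

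**Figure D1:**
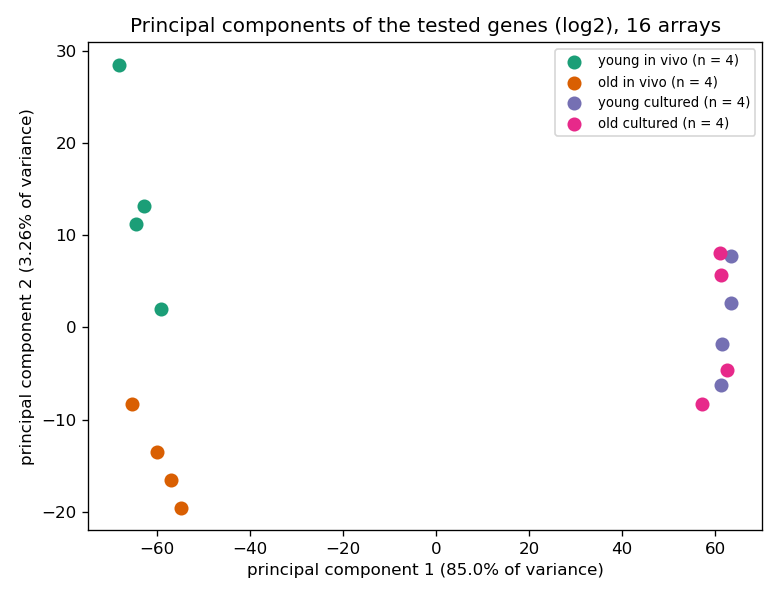
Scores of the 16 arrays on the first 2 principal components of the tested genes (log2 values, centred per gene), coloured by group with n = 4 each. Cultured and in vivo arrays lie apart along the first component (85.0% of the variance), and along the second (3.26%) the in vivo arrays of the 2 ages do not overlap.

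The first comparison asked how cultured cells differed from freshly isolated cells. Cultured fibroblasts of both ages had higher levels of contractile genes than fresh cells. Tpm2, a tropomyosin of actin filaments, was 83.6-fold higher in cultured than in vivo cells (log2 change 6.38 ± 0.10, n = 8 per condition). Acta2, the smooth muscle actin that marks myofibroblasts, was 61.5-fold higher (5.94 ± 0.12), and Tnc, a matrix glycoprotein of healing wounds, 49.3-fold higher (5.62 ± 0.12). Hmga2, a chromatin protein of embryonic and proliferating cells, rose 49.5-fold (5.63 ± 0.23), and Rrm2, the ribonucleotide reductase subunit that supplies deoxynucleotides for DNA synthesis, 45.6-fold (5.51 ± 0.09). In the opposite direction, the small GTPase gene Gem fell by 5.19 ± 0.09, Lum, a proteoglycan that organises collagen fibrils, by 4.64 ± 0.11, C1s1, a protease of the first complement component, by 4.61 ± 0.17, and Iigp1, an interferon-induced GTPase, by 4.71 ± 0.33.

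The other named genes that rose were Npnt, Actg2, Prl2c2, Steap1, Actn1, Inhba, Ccn2, Cnn1, Acta1 and Cdca8, with log2 changes of 4.88 to 5.99. Those that fell were Gda, Amy1, Ptgfr, Abi3bp, Galnt15, Tnfaip6, Scara5, Olfml1, Lepr, Abca8a and Entpd2, with changes of -5.06 to -4.39. For 8 of these 30 genes (Npnt, Actg2, Ccn2, Cnn1, Gda, Amy1, Abi3bp and Iigp1) the lower group lay within the range of the control probe sets, so their changes are underestimates. Of 14819 genes, 11787 passed the threshold, 5156 higher and 6631 lower in culture, and 3167 of them changed at least 2-fold (1966 higher, 1201 lower). The values of 6680 genes did not overlap between the conditions. The share of calls that were higher was 43.7%, against 29.5% after scaling to the 75th percentile and 48.2% after cyclic loess.

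The gene lists for cell division and contraction rose. All 23 measured mitosis genes were higher in culture (median log2 change 3.17, adjusted p = 4.57e-14), among them Ccna2, the cyclin of S phase and mitosis (4.64 ± 0.11), Anln (4.31 ± 0.06) and Birc5 (4.26 ± 0.10). Of 24 DNA replication genes 23 were higher and 1 did not pass (median 2.04, adjusted p = 1.67e-10; adjusted p = 0.104 with an estimated correlation), including the helicase subunits Mcm2 (4.31 ± 0.12) and Mcm5 (3.95 ± 0.13). All 18 myofibroblast and contractile genes were higher (median 2.62, adjusted p = 1.88e-11), led by Tpm2, Acta2, Actg2 and Actn1. Targets of YAP and TAZ, transcriptional coactivators that respond to cell tension, were higher for 13 of 16 genes and lower for 3 (median 1.77, adjusted p = 3.49e-04). Among these were Ccn2 (5.16 ± 0.14) and Ankrd1 (4.24 ± 0.22), while Nt5e fell by 3.11 ± 0.10. The calls of the mitosis, contractile and YAP/TAZ lists held with an estimated correlation (adjusted p = 0.00746, 0.0125 and 0.0397).

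Lists of growth and metabolism were higher as well. Ribosome biogenesis had 21 of 22 genes higher and none lower (median 1.15, adjusted p = 5.11e-08; adjusted p = 0.0815 with an estimated correlation), such as Wdr12 (2.99 ± 0.14) and Nhp2 (2.53 ± 0.10). All 22 proteasome genes were higher (median 0.96, adjusted p = 3.22e-09; adjusted p = 0.156 with an estimated correlation), with Psmd14 at 1.73 ± 0.07. Oxidative phosphorylation had 25 of 26 genes higher and 1 lower (median 0.64, adjusted p = 3.54e-07; adjusted p = 0.127 with an estimated correlation), with Cox5a at 2.06 ± 0.11. Glycolysis had 11 of 17 higher, 1 lower and 5 not past the threshold (median 0.78, adjusted p = 0.00182; adjusted p = 0.175 with an estimated correlation), with the lactate exporter Slc16a3 at 2.43 ± 0.13 and Pgk1 at 2.08 ± 0.08. Cholesterol synthesis had 13 of 17 higher, 1 lower and 3 not past it (median 1.15, adjusted p = 6.13e-04; adjusted p = 0.311 with an estimated correlation), with Sqle, an early committed enzyme of the sterol branch, at 3.80 ± 0.22 and Fdps at 2.73 ± 0.24. NRF2 antioxidant genes had 13 of 19 higher, 4 lower and 2 not past it (median 0.96, adjusted p = 0.00594; adjusted p = 0.193 with an estimated correlation). Nqo1, a quinone reductase, rose by 3.17 ± 0.22 on the log2 scale, and the secreted superoxide dismutase Sod3 fell by 3.19 ± 0.16. Cytosolic ribosomal proteins had 16 of 22 higher, 1 lower and 5 not past it (median 0.18, adjusted p = 0.00282; adjusted p = 0.328 with an estimated correlation), and the call was lost after scaling to the 75th percentile and after cyclic loess. Their median was -0.09 after the former, which moved the median of all genes by -0.28, and 0.03 after the latter.

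Genes of innate defence and inflammation were lower in cultured than in freshly isolated cells. A change during isolation of the fresh cells and a change during culture cannot be told apart here. All 20 interferon response genes were lower (median -2.45, adjusted p = 5.63e-08; adjusted p = 0.104 with an estimated correlation), for example Gbp2 (-4.37 ± 0.24) and the transcription factor Irf1 (-3.51 ± 0.13). All 11 genes of MHC class I and antigen processing were lower (median -1.97, adjusted p = 1.55e-06; adjusted p = 0.0823 with an estimated correlation), such as H2-Q4 (-4.34 ± 0.18) and Psmb8 (-3.92 ± 0.10), a subunit of the immunoproteasome. Of 14 complement genes 13 were lower and 1 did not pass (median -3.32, adjusted p = 2.02e-06, and 0.0397 with an estimated correlation), including C1ra (-4.17 ± 0.12) and C4b (-4.04 ± 0.15). The NF-kB pathway had 15 of 19 genes lower and 2 higher (median -1.50, adjusted p = 8.00e-05; adjusted p = 0.0915 with an estimated correlation), with the adhesion molecule Icam1 at -4.09 ± 0.14 and the inhibitor Nfkbia at -2.64 ± 0.08. Immediate early genes, which respond to stimuli within minutes, had 16 of 21 lower and 4 higher (median -1.43, adjusted p = 6.39e-05; adjusted p = 0.127 with an estimated correlation), with Atf3 at -3.28 ± 0.09 and Fos at -2.41 ± 0.07. Secreted inflammatory factors had 14 of 19 lower and 4 higher (median -0.45, adjusted p = 0.0419; adjusted p = 0.284 with an estimated correlation). The chemokine Ccl11 was at -3.99 ± 0.08, whereas Ptgs2, the inducible enzyme of prostaglandin synthesis, rose by 4.85 ± 0.29. The call of the secreted factors was lost after scaling to the 75th percentile (adjusted p = 0.200), after cyclic loess (0.0680) and with the mean over probe sets (0.0577). It was also lost without old cultured replicate 3 (0.0540) and without the least correlated in vivo arrays (0.0505).

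Lists of fibroblast identity and of the tissue environment fell too. Wnt pathway genes were lower for 15 of 19 and higher for 1 (median -1.16, adjusted p = 0.00182; adjusted p = 0.0535 with an estimated correlation), with the Wnt target Axin2 at -2.81 ± 0.07. The IGF axis had 8 of 11 genes lower and none higher (median -1.60, adjusted p = 0.00254; adjusted p = 0.0815 with an estimated correlation), with Igf1 at -2.73 ± 0.16 and Igfbp5 at -3.34 ± 0.15. Markers of papillary fibroblasts, those of the upper dermis, were lower for 10 of 13 and higher for 1 (median -0.65, adjusted p = 0.00133; adjusted p = 0.0815 with an estimated correlation), among them Dpp4 (-3.55 ± 0.09) and Ntn1 (-4.13 ± 0.08). Reticular and hypodermal markers were lower for 8 of 11 and higher for 1 (median -0.71, adjusted p = 0.0253; adjusted p = 0.216 with an estimated correlation), with Dpep1 at -3.06 ± 0.20 and Dlk1 at 1.71 ± 0.39, and lost the call after scaling to the 75th percentile. Circadian clock genes were lower for 14 of 17 and higher for 1 (median -0.77, adjusted p = 0.00282; adjusted p = 0.127 with an estimated correlation), with Rora at -2.94 ± 0.11. Lysosome and autophagy genes were lower for 17 of 19 and higher for 1 (median -0.59, adjusted p = 3.22e-04; adjusted p = 0.0815 with an estimated correlation), with Ctsk at -1.65 ± 0.06. Matrix glycoproteins and proteoglycans were lower for 15 of 25 and higher for 5 (median -0.51, adjusted p = 0.0412; adjusted p = 0.485 with an estimated correlation). Here Lum fell while Tnc and Fbln2 (3.17 ± 0.11) rose. The call was lost after scaling to the 75th percentile (adjusted p = 0.0893), without genes that other lists share (0.0529) and without young in vivo replicate 1 (0.0542).

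The remaining lists held genes that went both ways and did not pass the camera test as a whole. Collagens had 8 higher, 10 lower and 1 not past the threshold of 19 (median -0.29, adjusted p = 0.628), with Col8a1 at 1.72 ± 0.09 and Col14a1 at -3.53 ± 0.17. Collagen processing enzymes had 6 higher, 6 lower and 4 not past it of 16 (adjusted p = 0.587), with Loxl3 at 3.81 ± 0.12 and Pcolce2 at -2.59 ± 0.10. Metalloproteinases and inhibitors had 4 higher and 10 lower of 16 (adjusted p = 0.0864), with Timp1 at 3.59 ± 0.11 and Mmp3 at -3.43 ± 0.15. Genes of p53 and cell cycle inhibition had 12 higher and 6 lower of 19 (adjusted p = 0.0669), with Cdkn2b at 2.05 ± 0.13 and Cdkn1c at -3.01 ± 0.19. Adipogenesis had 7 higher and 10 lower of 20 (adjusted p = 0.880), with the fatty acid binding proteins Fabp5 at 4.84 ± 0.16 and Fabp4 at 4.32 ± 0.35. The TGF-beta and BMP list had 10 higher and 7 lower of 20 (adjusted p = 0.628), with Inhba at 5.29 ± 0.17 and Bmp4 at -4.17 ± 0.10. Hypoxia response had 7 higher and 5 lower of 19 (adjusted p = 0.650), the unfolded protein response 10 higher and 3 lower of 21 (adjusted p = 0.277), and heat shock chaperones 6 higher and 5 lower of 13 (adjusted p = 0.420). HOX and limb identity genes had 4 higher and 8 lower of 22 (adjusted p = 0.338) and imprinted growth genes 3 higher and 6 lower of 11 (adjusted p = 0.146). Adjusted over the list alone, the counts of members higher and lower were the same in all 35 lists.

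**Figure D2:**
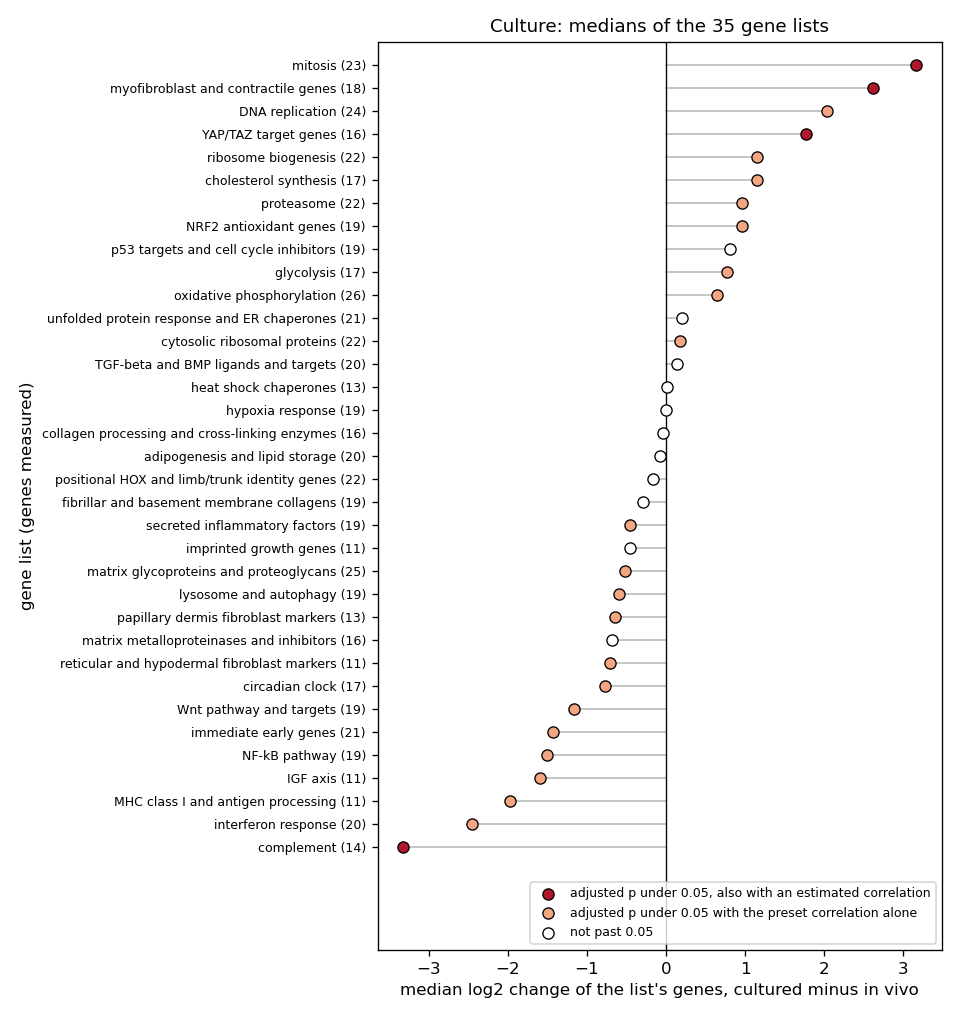
Median log2 change (cultured minus in vivo, n = 8 arrays per condition) of the measured genes of each of the 35 gene lists, with the number of genes measured in parentheses. Filled points passed the camera test at an adjusted p under 0.05, and dark points also with an estimated correlation. Mitosis (3.17) and complement (-3.32) stand at the ends, and the small positive median of the cytosolic ribosomal proteins (0.18) was -0.09 after scaling to the 75th percentile, which moved the median of all genes by -0.28.

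Markers of other cells and the 3' to 5' difference of beta-actin (from -0.41 to 0.07 in young and from -0.46 to 0.10 in old cells) also moved with culture. The macrophage and monocyte list had 10 of 12 genes lower in culture and none higher (1 higher adjusted over the list alone; median -0.44, adjusted p = 0.0252; adjusted p = 0.272 with an estimated correlation), with Cd68 at -2.59 ± 0.20 and Lyz2 at -1.04 ± 0.09. That call was lost after scaling to the 75th percentile and after cyclic loess. The fibroblast markers themselves had 8 of 9 genes lower and none higher (median -0.50, adjusted p = 0.00859; adjusted p = 0.305 with an estimated correlation), with Dpt at -2.85 ± 0.08, Dcn at -1.68 ± 0.07 and Col1a2 at -1.28 ± 0.10. No other marker list passed. Keratinocyte markers had 7 lower and 1 higher of 11, endothelial markers 6 lower of 10 (5 adjusted over the list alone), melanocyte markers 6 lower of 6 (adjusted p = 0.0676) and T cell markers 7 lower of 7 (adjusted p = 0.191). Pericyte and smooth muscle markers had 3 higher and 2 lower of 8, dendritic cell markers 6 lower and 1 higher of 8, and neutrophil markers 4 lower of 6 (2 adjusted over the list alone). Leukocyte markers had 4 lower and 2 higher of 6, skeletal muscle markers 6 lower and 1 higher of 9, and dermal papilla markers 3 lower and 2 higher of 6. Over all genes tested 6631 of 14819 were lower. Some of these markers were near background already in young and old in vivo samples, such as Cd3e (4.13 and 4.14) and Cd2 (4.27 and 4.25) of T cells, though Cd247 (6.09 and 6.27) was not. The counts therefore do not show a loss of these cells.

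Cultured and fresh cells differed in much the same direction at both ages. In young cells 10550 genes passed (4834 higher, 5716 lower) and in old cells 9301 (4478 higher, 4823 lower). Of these, 4153 genes were higher in both and 4154 lower in both, while 12 and 5 were called in opposite directions. Of the 35 lists, 24 passed in young and 23 in old cells, and with an estimated correlation 5 and 6. Cytosolic ribosomal proteins passed in young cells (17 of 22 higher, median 0.25, adjusted p = 8.13e-04; adjusted p = 0.265 with an estimated correlation) and not in old cells (median 0.12, adjusted p = 0.0561), but the age difference in this list's culture change is the interaction given further on.

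The second comparison asked which genes differed with age in freshly isolated cells. Bcat1, the cytosolic enzyme that starts the breakdown of branched-chain amino acids, was 17.3-fold lower in old than in young in vivo cells (log2 change -4.12 ± 0.17, adjusted p = 5.73e-10). Its log2 value was 8.60 ± 0.42 (SD, n = 4) in young and 4.48 ± 0.31 in old cells. Igf2, a growth factor of fetal growth whose gene is imprinted, was 4.84-fold higher in old cells (2.27 ± 0.20, adjusted p = 3.18e-06). The noncoding RNAs Rian and Mirg, transcribed from the imprinted locus next to Meg3, were lower in old cells (-2.55 ± 0.34 and -2.62 ± 0.44). Aldh1l2, a mitochondrial folate enzyme, was lower by a log2 change of -2.70 ± 0.21, and Creb3l3, a membrane-bound transcription factor known from the liver, by -2.67 ± 0.12.

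Other genes that were lower in old in vivo cells were Rassf4 (-2.43 ± 0.15), Cgref1 (-2.08 ± 0.15), Camk2a, Miat, Cmah, Obox2 and Cybrd1. Genes that were higher included Tmem176a (2.42 ± 0.36), Ntng1 (1.90 ± 0.12), the actin-severing protein Scin (1.89 ± 0.11), Csprs, the lactate dehydrogenase subunit Ldhb (3.64-fold, 1.86 ± 0.14), Syp, the thrombin receptor F2r, Plaat3, Tmem176b, Cd109 and Stac2. Aldh1l2 and Rassf4 lay within the range of the control probe sets in old cells, so their changes are underestimates. Cmah (-1.73 ± 0.48, adjusted p = 0.0409) rested on single arrays: without old in vivo replicate 1 its change was -1.15 (adjusted p = 0.0613), and without young in vivo replicate 4 it was -1.66 (adjusted p = 0.0901).

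In all, 900 genes passed, 665 higher and 235 lower in old cells, of which 81 changed at least 2-fold (35 higher, 46 lower). On simulated data with 200 changed genes 28.4% of the calls of this comparison were false, while 52.2% of genes with a log2 change of 0.5 were recovered. The false share depends on the number of genes changed and on genes being drawn independently, so it is not an estimate for the 900 genes. With only the 8 in vivo arrays in the fit, 200 genes passed (135 higher, 65 lower), 187 of them among the 900, and 21 of the 24 named genes. Csprs, F2r and Cmah were the named genes lost (adjusted p = 0.0554, 0.0745 and 0.0952). The values of 684 of the 900 genes did not overlap between the ages, and over all genes tested the share was 8.53%, against 2.86% by chance. The larger number of higher genes depended on the scaling: 73.9% of the calls were higher as deposited, 53.3% after cyclic loess and 39.2% after scaling to the 75th percentile. Leaving out young in vivo replicate 2 gave 557 genes, young in vivo replicate 3 gave 542, and old in vivo replicate 4 gave 559, while leaving out young in vivo replicate 1 gave 1230.

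**Figure D3:**
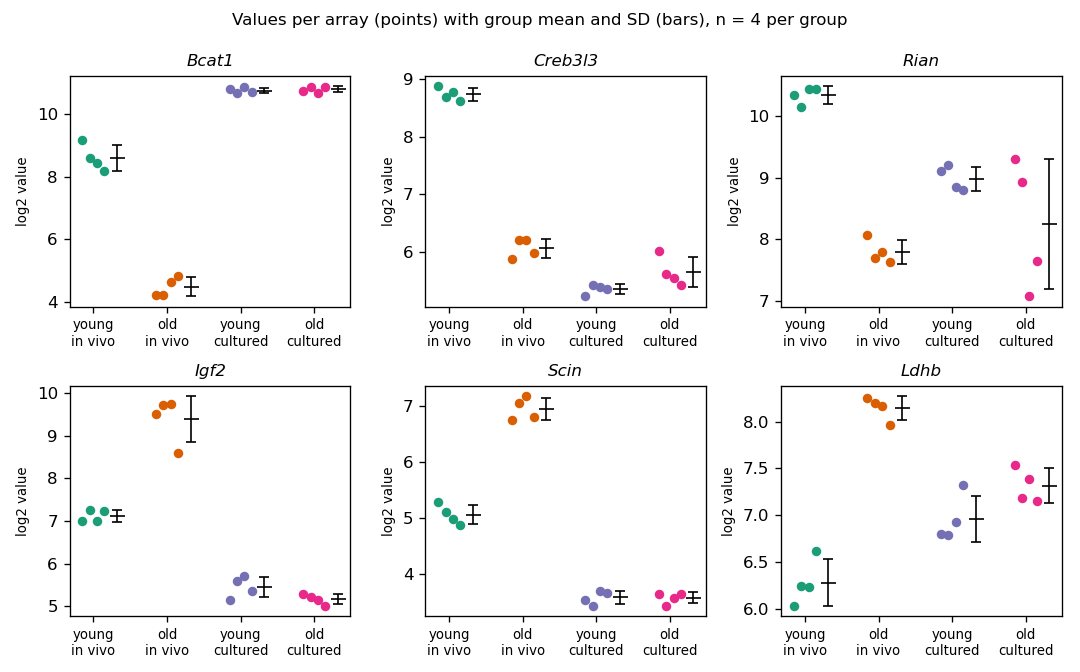
Log2 values of 6 genes on each array (points), with the group mean and SD (bars), n = 4 per group. For Bcat1, Creb3l3, Rian, Igf2, Scin and Ldhb the young and old in vivo values do not overlap, while the cultured values of Bcat1 lie close together (means 10.76 in young and 10.80 in old).

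Collagen genes were the list with the largest shift with age in vivo. Of 19 genes 8 were lower, none higher and 11 did not pass, and 14 were lower when adjusted over the list alone (median -0.58, adjusted p = 6.84e-13, and 0.0411 with an estimated correlation). Among them were Col14a1, which binds the surface of collagen fibrils (-1.57 ± 0.24), Col7a1, which anchors the basement membrane to the dermis (-1.05 ± 0.25), Col4a2 (-0.73 ± 0.15) and Col15a1 (-0.73 ± 0.19). An exact permutation of the age labels of the 8 arrays, chosen after the data were seen, gave p = 0.0286 for the list's median, the smallest p that 4 against 4 arrays allow. The permutation was run only for lists already past the camera test on the same arrays, and its p-values are not adjusted over lists. It is therefore no separate support for these lists. Enzymes that modify and cross-link collagen had 6 of 16 genes lower and none higher, or 7 lower adjusted over the list alone (median -0.17, adjusted p = 5.93e-05; adjusted p = 0.436 with an estimated correlation; exact permutation p = 0.257). They included the cross-linking oxidase Lox (-0.93 ± 0.20) and the hydroxylases P4ha2 (-0.96 ± 0.21) and Plod1 (-0.67 ± 0.12).

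Complement genes had 4 of 14 higher in old in vivo cells and none lower, or 6 higher adjusted over the list alone (median 0.37, adjusted p = 9.59e-04; adjusted p = 0.396 with an estimated correlation; exact permutation p = 0.0286). These were C2 (1.26 ± 0.20), Cfb (1.19 ± 0.13), C4b (0.94 ± 0.21) and Clu (0.82 ± 0.21). Proteasome genes had 6 of 22 higher and 19 adjusted over the list alone (median 0.31, adjusted p = 2.05e-09; adjusted p = 0.511 with an estimated correlation; exact permutation p = 0.0571), with Psma1 at 0.47 ± 0.09. Cytosolic ribosomal proteins had 6 of 22 higher by either adjustment (median 0.15, adjusted p = 2.61e-06; adjusted p = 0.511 with an estimated correlation; exact permutation p = 0.0286), with Rps18 at 0.36 ± 0.07 and Rpl32 at 0.40 ± 0.09. Oxidative phosphorylation had 3 of 26 higher and 5 adjusted over the list alone (median 0.20, adjusted p = 1.36e-04; adjusted p = 0.516 with an estimated correlation; exact permutation p = 0.0571), with Ndufv1 at 0.33 ± 0.07. NRF2 antioxidant genes had 1 of 19 higher, Gclm of glutathione synthesis (0.59 ± 0.09), and 3 adjusted over the list alone (median 0.23, adjusted p = 0.0173; adjusted p = 0.516 with an estimated correlation; exact permutation p = 0.0571). Ribosome biogenesis had 0 of 22 past the threshold and 3 adjusted over the list alone (median 0.21, adjusted p = 0.00896; adjusted p = 0.604 with an estimated correlation; exact permutation p = 0.0286). The NRF2 call was lost after cyclic loess (median 0.12, adjusted p = 0.0714) and without old in vivo replicate 4 (median 0.13, adjusted p = 0.0885). The ribosome biogenesis call was lost after cyclic loess (median 0.11, adjusted p = 0.149), with fry (adjusted p = 0.0725) and without young in vivo replicate 4 (median 0.14, adjusted p = 0.137).

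The other 27 lists did not pass for age in vivo. Imprinted growth genes had 3 of 11 lower and 1 higher, or 4 lower adjusted over the list alone: Rian, the neighbouring noncoding RNA Meg3 (-1.56 ± 0.30, adjusted p = 0.00687) and Peg3 (-1.53 ± 0.23, adjusted p = 0.00116) against Igf2. Metalloproteinases had 3 of 16 lower (adjusted p = 0.0785 for the list), namely Adamts4 (-1.07 ± 0.24), Mmp3 (-0.94 ± 0.21) and Mmp2 (-0.31 ± 0.09). Secreted inflammatory factors had 2 of 19 higher, the chemokines Ccl19 (0.65 ± 0.16) and Ccl11 (0.44 ± 0.12). HOX genes had 2 of 22 higher, Hoxa10 (1.16 ± 0.31) and Hoxa9 (0.64 ± 0.16), and 3 adjusted over the list alone. No DNA replication gene and no gene of the p53 and cell cycle inhibitor list passed (0 of 24 and 0 of 19, also adjusted over the list alone). At an unadjusted p under 0.05, 2912 genes differed in the limma fit. None of the 12 marker lists passed (lowest adjusted p = 0.757). The 3' to 5' difference of Gapdh also moved with age in vivo (-0.08 in young, -0.14 in old). Single markers that passed were Csf1r (-1.07 ± 0.16) and Fcgr3 (-0.54 ± 0.10) of macrophages, Kcnj8 of pericytes (1.06 ± 0.19) and Col1a2 (-0.63 ± 0.14).

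The third comparison asked the same question after culture. No gene differed between old and young cultured cells at the threshold (0 of 14819 in limma, with 276 at an unadjusted p under 0.05). The smallest p-values belonged to Tcfl5 (-1.65 ± 0.26), Tfap2a (1.31 ± 0.21), a transcription factor of skin and neural crest, and Brinp1 (-1.71 ± 0.28), each with an adjusted p of 0.0723. The change of B4galt6 was -1.19 ± 0.22 (adjusted p = 0.206) and that of Csgalnact1, an enzyme of chondroitin sulfate synthesis, 1.02 ± 0.24 (adjusted p = 0.689). The values for Slc6a12, Samd9l and Mdga1 were 0.53, 0.43 and 0.36, and those for Cyp4a12a and Scara5 -0.68 and -0.62, none of them past the threshold. Tcfl5 and Cyp4a12a in old cultured cells, Slc6a12 in young and Samd9l in both lay within the range of the control probe sets, so these differences rest on signals near background. Bcat1, which differed most in vivo, stood at 10.76 ± 0.09 (SD, n = 4) in young and 10.80 ± 0.09 in old cultured cells. Between 0 and 5 genes passed when 1 array was left out, the 5 without old cultured replicate 3, and Tcfl5, Brinp1 and Tfap2a passed with the filter at the median of all values (adjusted p = 0.0495), and Tcfl5 and Tfap2a after scaling to the 75th percentile (0.0444).

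Of the 35 lists 3 passed, all with small negative medians and with 0 members past the threshold, also adjusted over the list alone. They were mitosis (23 genes, median -0.09, adjusted p = 0.0304), imprinted growth genes (11 genes, median -0.23, adjusted p = 0.0304) and immediate early genes (21 genes, median -0.08, adjusted p = 0.0391). Each had an adjusted p of 0.941 with an estimated correlation, and exact permutation gave p = 0.0571, 0.143 and 0.314. Their calls were lost after cyclic loess and without single cultured arrays. The median was -0.02 for mitosis without old cultured replicate 3 (adjusted p = 0.235), -0.14 for imprinted growth genes without old cultured replicate 4 (0.494) and -0.05 for immediate early genes without young cultured replicate 4 (0.419). In the lists that did not pass, 1 HOX gene was higher, and 1 collagen and 1 IGF axis gene were lower, adjusted over the list alone. Among marker lists the pericyte and smooth muscle list passed (8 genes, median -0.09, adjusted p = 4.63e-04, and 0.0188 with an estimated correlation; exact permutation p = 0.0857). Its members with the largest changes were Myh11 (-0.84 ± 0.19) and Actg2 (-0.49 ± 0.22), which did not pass.

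The last comparison tested whether the age difference itself changed with culture. For Bcat1 the age difference in culture exceeded that in vivo by a log2 value of 4.15 ± 0.25 (adjusted p = 6.23e-08), since the cultured cells of both ages had similar levels. Creb3l3 (2.97 ± 0.17), Aldh1l2 (2.76 ± 0.29), Rassf4, Cgref1 (2.23 ± 0.21), Camk2a, Emid1 and Obox2 also had positive values. Their lower level in old cells in vivo was small, absent or turned in culture, with age differences there such as 0.30 for Creb3l3, 0.06 for Aldh1l2 and -0.10 for Camk2a. Rassf4 lay within the range of the control probe sets in culture (3.41 in young, 3.48 in old), as did Scin (3.58 in both), so no age difference could be seen there, and Aldh1l2 lay within it in old in vivo cells. The value of Obox2 (1.60 ± 0.35, adjusted p = 0.0493) did not pass with the mean over its probe sets (0.65, adjusted p = 0.149) or without young cultured replicate 4 (0.114). With the mean over probe sets the values of Syp (-0.81, adjusted p = 0.0633) and Slc9a3r1 (-1.10, adjusted p = 0.0629) did not pass either. Nor did Syp without old cultured replicate 4 (0.0691) and Slc9a3r1 without old cultured replicate 2 (0.0579). Igf2 had a value of -2.56 ± 0.28 (adjusted p = 1.24e-04), and Scin, Ntng1, Syp, Slc9a3r1, Cd109, Ldhb and Plaat3 lay between -1.90 and -1.48. In all 87 genes passed, 29 positive and 58 negative. Of the 58, 57 were higher with age in vivo, and all 29 were lower with age in vivo, which follows in part from the in vivo arrays that both contrasts share. The split depended on the scaling: 33.3% were positive as deposited, 47.7% after cyclic loess and 65.3% after scaling to the 75th percentile. The count was 161 without young in vivo replicate 1 and 200 without old in vivo replicate 1. It was 55 without young cultured replicate 1 or 2, 44 without young cultured replicate 4, 48 without old cultured replicate 2 and 53 without old cultured replicate 4.

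The 8 lists that passed for age in vivo passed for the interaction with the opposite sign, which the shared in vivo arrays give wherever the age difference in culture is small. Collagens had a median of 0.54 (2 of 19 positive, 11 adjusted over the list alone, adjusted p = 1.80e-09; adjusted p = 0.122 with an estimated correlation), with Col14a1 at 1.59 ± 0.34 and Col5a2 at 0.67 ± 0.14. Complement had a median of -0.32 (2 of 14 negative, 4 adjusted over the list alone, adjusted p = 0.00617; adjusted p = 0.536 with an estimated correlation), with Cfb at -1.36 ± 0.19 and C2 at -1.33 ± 0.29. The proteasome had a median of -0.34 (0 of 22, 9 adjusted over the list alone, adjusted p = 8.54e-09) and NRF2 genes one of -0.32 (1 of 19, Gclm at -0.83 ± 0.12, also 1 adjusted over the list alone, adjusted p = 0.00959), each with an adjusted p = 0.536 with an estimated correlation. Ribosomal proteins (median -0.16, adjusted p = 4.76e-05), ribosome biogenesis (-0.24, adjusted p = 0.00203), oxidative phosphorylation (-0.20, adjusted p = 0.00203) and collagen processing (0.24, adjusted p = 9.16e-04) had 0 members past the threshold in the limma fit, where 1823 genes passed at an unadjusted p under 0.05. Adjusted over the list alone, 4 collagen processing genes and 1 ribosomal protein gene passed, and none of the other lists' genes. With an estimated correlation the adjusted p was 0.551 for oxidative phosphorylation and 0.536 for the ribosomal protein, ribosome biogenesis and collagen processing lists. After cyclic loess the calls of oxidative phosphorylation, NRF2 genes and ribosome biogenesis were lost (adjusted p = 0.0506, 0.0578 and 0.0584), and that of NRF2 genes also without old in vivo replicate 4 (0.0524).

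**Figure D4:**
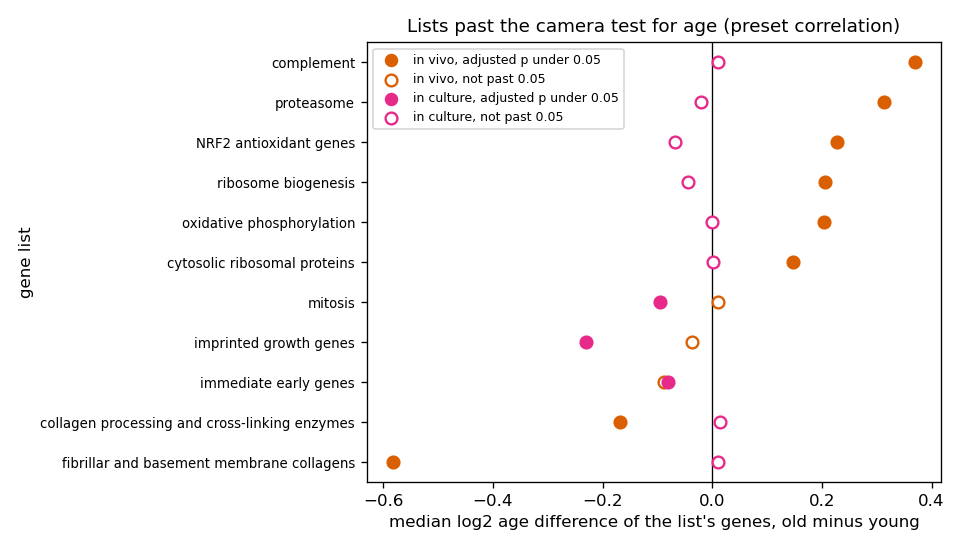
Median log2 age difference (old minus young, n = 4 per group) of the genes of the 11 lists past the camera test with the preset correlation in vivo or in culture. Filled points passed, and collagens (-0.58 in vivo, 0.01 in culture) and complement (0.37 in vivo, 0.01 in culture) stand at the ends.

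Across all genes the age difference in culture was not correlated with that in vivo (r = -0.0017, exact permutation p = 0.971; rho = -0.067, exact permutation p = 0.714). Genes are not independent replicates, so p comes from permuting the age labels of the cultured arrays. Over the 900 genes past the threshold in vivo, r was 0.086 (exact permutation p = 0.4) and rho -0.024 (exact permutation p = 0.771). In culture 404 of these 900 genes (44.9%) had the sign they had in vivo, 284 of the 665 higher and 120 of the 235 lower genes, and 15 of them at an unadjusted p under 0.05. Some genes had differences in culture of the sign they had in vivo, none past the threshold over all genes (adjusted p = 1). These were Meg3 (-0.64 ± 0.30), Rian (-0.74 ± 0.34), Mirg (-0.87 ± 0.44), Hoxa10 (1.18 ± 0.31) and Col15a1 (-0.69 ± 0.19) in culture, and their interaction did not pass either (adjusted p = 0.399, 0.102, 0.241, 0.991 and 0.966). All 5 were singled out here after their values in culture were seen. For Rian and Mirg the SD was 1.05 and 1.32 in old cultured cells, against 0.20 and 0.21 in young cultured cells.

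**Figure D5:**
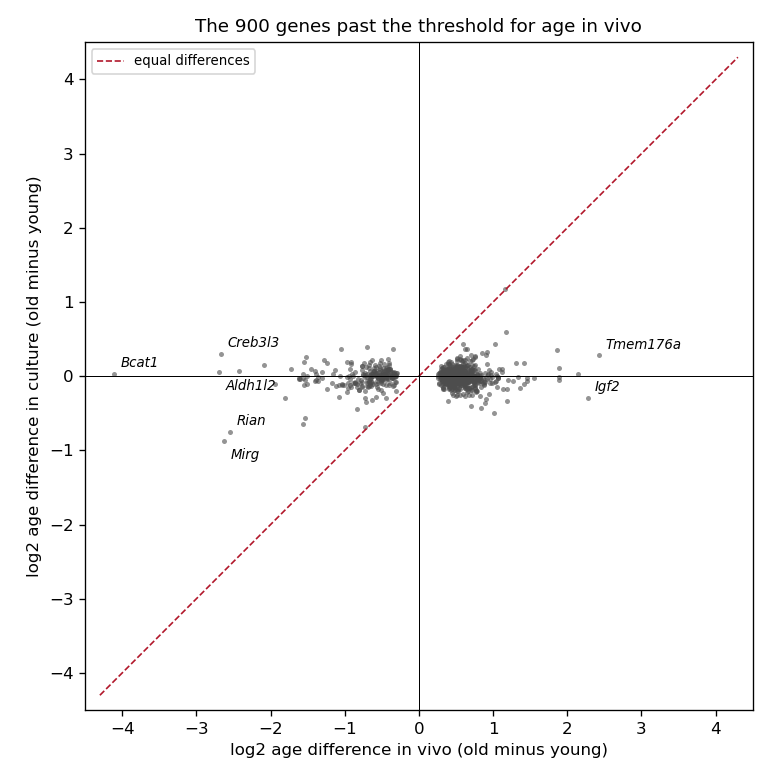
Log2 age difference (old minus young, n = 4 per group) in culture against that in vivo for the 900 genes past the threshold for age in vivo, with the line of equal differences dashed. Most points lie along the horizontal axis, with Bcat1 at -4.12 in vivo and 0.03 in culture.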

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

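The tests of an unlabelled split of the cultured arrays, of markers of other cell types, of a sequence difference between the mice and of exchanged labels were chosen after the result was seen. The other tests here were chosen before their own results were known. Those of hidden age differences and of the proteasome, ribosomal protein and oxidative phosphorylation lists were chosen after the main results that they address.

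The age difference of 16 named genes differed between culture and in vivo by the interaction test. The values (log2, culture minus in vivo) were 4.15 for Bcat1, 2.97 for Creb3l3, 2.76 for Aldh1l2, 2.5 for Rassf4, 2.23 for Cgref1, 1.84 for Camk2a, 1.75 for Emid1 and 1.6 for Obox2. They were -2.56 for Igf2, -1.90 for Scin, -1.79 for Ntng1, -1.59 for Syp, -1.52 for Slc9a3r1, -1.52 for Cd109, -1.51 for Ldhb and -1.48 for Plaat3. With the mean over probe sets Obox2 (0.65), Syp (-0.81) and Slc9a3r1 (-1.10) did not pass, nor did each without 1 of the cultured arrays. Of gene lists, 8 differed in the same test, with medians of 0.54 for collagens, 0.24 for collagen processing, -0.32 for complement, -0.20 for oxidative phosphorylation, -0.32 for NRF2 genes, -0.34 for the proteasome, -0.16 for ribosomal proteins and -0.24 for ribosome biogenesis. With an estimated correlation 0 of the 8 passed (adjusted p = 0.122 for collagens, 0.536 to 0.551 for the others), and with fry 1 did.

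Most age differences of fresh cells were not seen after culture, though Meg3, Rian and Mirg kept their direction there (-0.64, -0.74 and -0.87, adjusted p = 1) and their interaction did not pass. The old cultured values scattered widely for Rian (SD 1.05, against 0.20 in young cultured cells) and Mirg (1.32 against 0.21). Differences of the same size, hidden by the spread between cultured arrays, would give a slope of cultured on in vivo differences near that between 2 sets of in vivo arrays (2 per age in each), but it was 0.0147 (-0.0064 to 0.0402) against 0.537 (0.365 to 0.744), lower in 36 of 36 splits. With an unlabelled split of the cultured arrays as a block, which may be the collection day, 0 genes passed for age in culture in limma, and the block raised the count at an unadjusted p under 0.05 from 533 to 883 on these 8 arrays. The split holds as many young as old arrays, so it leaves the differences and their low slope as they are. For these genes as a set the slope argues against hidden differences of the same size but not against smaller ones. Genes near background in culture, such as Scin (3.58 in both ages), were kept in the slope and lower it. How far they do so was not tested, and for them the slope decides nothing. Other cell types in fresh samples of one age stay open: 2.73% of their markers passed for age in vivo (3 of 110, against 6.07% of all genes, one-sided Fisher's exact p = 0.967), but not all could show a change (76 of the 110 lay above the control probe sets), Csf1r and Fcgr3 were lower and Kcnj8 higher in old samples, and an age difference that fibroblasts lose in culture and the loss of some fibroblasts during culture were not tested.

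The largest age differences might stem from a sequence difference between young and old mice, such as a substrain difference. Over the 22 named genes with cultured levels above the control probe sets, the median ratio of the cultured to the in vivo age difference was 0.00192 (range -0.126 to 0.332, the highest for Mirg), and 0 reached 0.5. Some of the 22 lay little above the control level (4.34) in culture, such as Ntng1 (4.52) and Csprs (4.57), so their ratios, narrowed by background, decide little. Choosing genes for a large in vivo difference also lowers the ratio. Brighter cultured genes included Bcat1 (10.78, ratio -0.0085), F2r (10.885, -0.0446), Aldh1l2 (8.95, -0.0222) and Rian (8.61, 0.292). A sequence difference that acts in all of a mouse's cells would be carried into culture. For Bcat1 and Aldh1l2, whose interaction passed, the values argue against it. The interaction did not pass for F2r (limma adjusted p = 0.0969), Rian or Mirg, and the differences of Rian and Mirg kept their sign in culture. For these genes and the dim ones it stays open. A sequence difference that acts in fresh cells alone stays open, as does an effect of age.

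Proteasome, ribosomal protein and oxidative phosphorylation genes were slightly higher in old fresh cells. A narrower range of values on the young in vivo arrays could lift all bright genes, but among 10000 random lists matched on mean expression the medians stood at the 99.75th percentile or above. The random lists rose too, with medians of 0.0925, 0.0275 and 0.0838 against 0.31, 0.15 and 0.20. The percentile takes genes as independent, and the lists were chosen for their shift on these same arrays. After cyclic loess, which evens out such differences, all 3 lists passed in the same direction (adjusted p = 8.07e-09, 5.55e-05 and 0.00680), with medians of 0.22, 0.12 and 0.12. The camera calls of NRF2 genes (adjusted p = 0.0714) and ribosome biogenesis (0.149), also slightly higher in old fresh cells, were lost after cyclic loess. For the 3 lists the values left after cyclic loess argue against the range of values and the scaling as the whole cause. For NRF2 genes and ribosome biogenesis both stay open. An effect of age and differences in RNA quality stay open, since the 3' to 5' difference of Gapdh did not overlap between young (-0.12 to -0.04) and old (-0.17 to -0.13) fresh samples, and the lists' calls were lost with an estimated correlation.

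Other splits of the same arrays into groups of the same sizes were counted, the real split included. The real split gave the most genes for culture in young (1 of 35 splits as large, 10550 genes, highest other 0), culture in old (1 of 35, 9301 genes, highest other 1) and culture (1 of 100, 11787 genes, highest other 7958). No other split came near it for culture in young or in old, so chance is unlikely, although 35 splits allow no smaller share. For culture 4 of the 100 splits, the real one included, kept the labels of the young arrays as given. For age in vivo the real split also gave the most genes (1 of 35, 900 genes, highest other 688). That is the smallest share that 35 splits allow, and another split came near it, so chance is less likely but not excluded. For the interaction 5 of 100 splits gave as many (87 genes, highest other 159), so chance cannot be excluded by this count. These 5 were all of the drawn splits that kept the in vivo labels as given, and with them the in vivo age difference, and none of the others gave as many. For age in culture 35 of 35 splits gave as many as the 0 genes of the real split. One of them, replicates 1 and 2 of both ages against replicates 3 and 4, gave 404 genes, which points to a structure of these samples other than age.

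For the number of gene lists past the camera test chance cannot be excluded in any of these comparisons. As many lists came from 14 of 35 splits for age in vivo (8 lists, highest other 13), 23 of 35 for age in culture (3 lists, highest other 12), 5 of 100 for culture (24 lists, highest other 25) and 39 of 100 for the interaction (8 lists, highest other 14). The highest other split for age in vivo genes exchanged young in vivo replicate 1 and old in vivo replicate 1. With these labels exchanged, 20 genes passed with at least a 2-fold change, against 81 as labelled, and 112 of the 688 genes were among the 900. This argues against exchanged labels, but without both arrays 1685 genes passed.

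Single samples stood apart from their group in 13 of 292 groups of 4 values (4.45%), and chance gives about 1 in 20. In vivo these were Obox2 in young replicate 2 (9.52, others 9.98 to 10.07), Cdca8 in old replicate 4 (4.83, others 4.40 to 4.47), Olfml1 in old replicate 1 (10.33, others 9.78 to 9.82), Cmah in old replicate 1 (5.22, others 7.30 to 7.65) and the hybridisation control BioB in old replicate 2 (9.14, others 8.33 to 8.43). In culture they were Tpm2 in young replicate 2 (11.7, others 11.52 to 11.55), Stac2 in young replicate 1 (6.03, others 5.47 to 5.52), Slc6a12 in young replicate 3 (4.3, others 4.20 to 4.21), Amy1 in old replicate 1 (3.9, others 4.05 to 4.07), Cmah in old replicate 3 (5.33, others 6.60 to 6.79) and Csgalnact1 in old replicate 3 (6.93, others 7.5 to 7.57). The array median stood apart in young cultured replicate 4 (4.76, others 4.75) and old cultured replicate 2 (4.74, others 4.76). Of 11274 tested probe sets with no gene name, which the comparisons do not use, 366 passed for age in vivo (219 higher, 147 lower), or 3.25% against 4.83% of named probe sets.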

How the results depend on the processing

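Weights per culture condition, leaving out the least correlated in vivo arrays, the block for the cultured split and the fits of gene lists on their own 8 arrays were chosen after the data were seen. No paired analysis was possible because the labels do not say which samples share a mouse. All 450 values of named culture genes kept their direction and side of the threshold. For age in vivo 349 of named genes' values did and 11 did not pass, and for the interaction 212 did and 12 did not pass. For age in culture 133 stayed short of the threshold and 14 passed. Of called lists' values for age in vivo, 84 stayed past the threshold and 12 did not, for culture 251 and 35, for culture in young 257 and 29, for culture in old 237 and 27, for age in culture 20 and 28, and for the interaction 69 and 19. No named gene's value changed direction. Of the lists' medians, that of cytosolic ribosomal proteins turned to -0.09 for culture and for culture in young after scaling to the 75th percentile, which moved the median of all genes by -0.28 and -0.34. Signal over background limits the dim genes, as 3687 genes had a group mean within the range of the control probe sets. For the values that follow, the cause was not tested except where fewer arrays, more probe sets or a stricter threshold shows it.

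With every probe set tested, 27813 passed for culture, 24685 for culture in young, 21805 for culture in old, 1560 for age in vivo, 2 for age in culture and 156 for the interaction. With at least a 2-fold change the counts were 3167, 3433, 3005, 81 and, for the interaction, 43. At an adjusted p under 0.01 they were 252 for age in vivo and 27 for the interaction. With 1 weight per culture condition 372 genes passed for age in vivo and 1 for age in culture, and with only the 8 in vivo arrays 200. For age in culture 3 passed with the filter at the median, 2 after scaling to the 75th percentile and 1 with array weights. For the interaction 185 passed with array weights and 162 without the least correlated arrays.

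With an estimated correlation 4 lists passed for culture, 5 for culture in young, 6 for culture in old, 1 for age in vivo, 0 for age in culture and 0 for the interaction. For age in culture 0 lists passed with no filter, the mean over probe sets, cyclic loess, fry or without the least correlated arrays, and 1 after scaling to the 75th percentile or on its own 8 arrays. With fry 7 lists passed for age in vivo and 1 for the interaction. Of marker lists, 1 passed for culture and 1 for culture in young after either scaling, 0 for culture, young and old with an estimated correlation, and with fry 11 for culture, 10 in young, 9 in old and 0 for age in culture. The correlation of the age differences turned positive, at 0.0052 with the filter at the median, 0.011 with the mean over probe sets and 0.0090 after cyclic loess. The first component held 86.3% with the filter at the median, 85.6% with the mean over probe sets and 58.5% with each gene at unit variance.

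Leaving out each array in turn gave 11413 to 11883 genes for culture, 9747 to 10681 in young, 8384 to 9654 in old, 542 to 1230 for age in vivo, 0 to 5 for age in culture and 44 to 200 for the interaction. For age in culture 5 passed without old cultured replicate 3, and 1 without old cultured replicate 2 or 4 or young cultured replicate 3 or 4. List counts were 22 to 25 for culture, 24 in young, 21 to 24 in old, 7 to 11 for age in vivo, 7 to 11 for the interaction and 0 to 4 for age in culture (0 without young in vivo replicate 3, 1 without young cultured replicate 1). Marker list counts for culture in old were 1 to 3 (2 without young in vivo replicate 1 or old cultured replicate 2, 3 without old in vivo replicate 3). The correlation lay between -0.059 and 0.046, with 8 of 16 values positive, and the first component held 84.6% to 85.9%.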

Other observations

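Of the 665 genes higher in old in vivo cells, 394 were higher in culture (231 by chance) and 188 lower (298 by chance). Of the 235 genes lower in old cells, 58 were higher in culture (81.8 by chance) and 152 lower (105 by chance). These chance counts take genes as independent, which they are not, and across all genes permuted age labels often gave as strong a relation (exact permutation p = 0.4). The share of calls for age in vivo that were higher also turned with the scaling (73.9% as deposited, 39.2% after scaling to the 75th percentile). Among the first were Actn1, a cross-linker of actin filaments (0.88 ± 0.17 with age, n = 4 per group), and Fabp5, a fatty acid binding protein (0.92 ± 0.22). Genes of the second kind included Col14a1, Mmp3 and Sfrp2, a secreted Wnt modulator (-1.62 ± 0.44 with age).

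Some transcripts known from other cells of the skin were detected in fresh samples of both ages, and others were not. Of 110 such markers 76 lay above the control probe sets. Below the control level (4.34) in young and old in vivo samples lay Emcn (4.08 and 3.98) and Tie1 (3.82 and 3.89) of endothelial cells. So did Ms4a7 of macrophages (4.18 and 4.14) and Epcam of keratinocytes (4.075 and 3.988). Single bright markers therefore do not show that these cells were present. Among the brighter markers, mean log2 values in young and old in vivo samples were 8.09 and 8.10 for Cd68 of macrophages and 6.91 and 7.25 for Krt10 of keratinocytes. They were 6.57 and 7.33 for the endothelial receptor Kdr and 10.19 and 10.35 for the globin Hba-a2. After culture Hba-a2 still stood at 9.61 and 9.59. None of Cd68, Krt10, Kdr and Hba-a2 passed the threshold for age in vivo (lowest adjusted p = 0.126, for Kdr). Of the 110 markers 3 did, namely Csf1r (-1.07 ± 0.16), Fcgr3 (-0.54 ± 0.10, near the control level) and Kcnj8 (1.06 ± 0.19). Of keratinocyte markers, Krt5 had an SD of 1.90 in old and 0.15 in young fresh samples, Krt14 of 1.14 and 0.14 and Perp of 1.16 and 0.04, whereas Trp63 had 0.46 and 0.48 and Epcam 0.065 and 0.196. These 5 were singled out after their values were seen, and no test of spread was run.

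The test of the shared direction of age and culture was chosen after the result was seen. That of neighbouring genes was chosen before its own result was known, but after the fall of Meg3, Rian and Mirg was seen. Differences in the range of values between the in vivo arrays might make age differences follow culture differences. Across all genes r between the 2 was 0.127 (exact permutation p = 0.4), and after cyclic loess 67.4% of it was left (r = 0.0855, exact permutation p = 0.429). The correlation was itself within what permuted age labels gave, so the share left cannot show whether the range of values caused it. Meg3, Rian and Mirg, which neighbour each other, were lower in old fresh cells, while nearby Dlk1 (-0.20, adjusted p = 0.881) and Dio3os (-0.26, adjusted p = 0.518) did not pass. Leaving out pairs with Meg3, Rian or Mirg, 48 of 14764 pairs of adjacent genes passed for age in vivo in the same direction, against a median of 33 (23 to 45) with genes shuffled, and 9 of 1000 shuffles gave as many. Neighbouring genes such as Cfb and C2, Tmem176a and Tmem176b, and Hoxa9 and Hoxa10 thus passed together more often than shuffled genes did. The age labels of the arrays were not permuted, and neighbours may vary together under any grouping, so this count cannot tie the excess to age. Shared regulation and probe sets that detect related sequences were not told apart.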
